A study of Mus musculus with 4 samples.

How the data were processed

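RNA sequencing of poly(A) RNA was analysed in 4 libraries of Ter119+ bone marrow cells of the mouse, 2 labelled Med16 fl/fl (floxed alleles) and 2 labelled Med16 KO, all with the time label of 3 weeks. Ter119 is an antigen of the erythroid lineage. Med16 encodes a subunit of Mediator, the complex that links transcription factors to RNA polymerase II. Per the labels' protocols, RNA was extracted with TRIzol, its quality was examined on a Bioanalyzer, and libraries were made with an Illumina mRNA kit.

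The deposited values are whole-number counts per gene, 1 table per library with a gene identifier, a symbol and a count. Per the submitters' processing notes, the tools FastQC 0.11.7, HISAT2 2.1.0, HTSeq 0.12.4, DESeq2 and HOMER were used with the mouse build GRCm39. The strand setting of the counting and the annotation release are not given in the sources used here. Counting of this kind leaves reads of near-identical copies and of overlapping genes unassigned or splits them, so globin and Hspa1 paralogs, immunoglobulin segments and genes with an antisense partner are reported as uncertain.

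The authors' tables list 56691 genes and 5 rows that name no gene. Those 5 rows were left out of library sizes and tests. In the order fl/fl 1, fl/fl 2, KO 1, KO 2, reads assigned to no feature made up 36.0%, 36.7%, 35.8% and 35.8% of all reads. Reads without a unique alignment made up 26.4%, 25.3%, 24.3% and 23.6%, and ambiguous reads 2.54%, 2.58%, 2.96% and 2.93%. Reads with low alignment quality made up 1.79%, 1.96%, 1.69% and 1.70%, and reads not aligned 1.05%, 0.826%, 2.69% and 3.27%. With the strand setting unknown, reads assigned to no feature may include reads on the opposite strand of annotated genes. Counts assigned to genes totalled 7216333, 7048208, 6948951 and 6749196 in the same order. At these depths 1 count equals 0.139 to 0.148 CPM (counts scaled to library size), and the limit that a count of 0 allows, taken as 3 counts per library, lies between 0.416 and 0.444 CPM of assigned counts. Intervals and floors cover counting error only.

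Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr by genotype, libraries were scaled with TMM, whose factors were 0.982, 0.981, 1.03 and 1.01, and Med16 KO was compared with Med16 fl/fl by the quasi-likelihood test with genotype as the only term. The test was two-sided, p values were adjusted by the Benjamini-Hochberg method over all 13052 genes tested, and genes were called at an adjusted p under 0.05. The common biological coefficient of variation was 0.125, with 2 residual and 13.1 prior degrees of freedom. CPM values are TMM-scaled and given as mean ± SD over the 2 libraries of a genotype. The SE of a log2 fold change was computed as its size divided by the square root of the F statistic.

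Before the data were examined, 32 gene lists were fixed: pathway and quality lists suited to erythroid cells and to Mediator, and markers of other bone marrow cells that such a sort could hold. The 31 lists with at least 5 genes tested were compared with all other genes by camera in limma 3.58.1, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. None of the 17 calls held with an estimated correlation, and that adjusted p is given beside each. That setting tests each list on the 2 residual degrees of freedom, so hardly any list could pass the adjustment. It therefore cannot decide whether correlation between genes accounts for a call. The genes named were taken from Med16; the 10 largest rises and the 10 largest falls among called genes whose genotypes did not overlap, with a mean of at least 5 CPM in the higher genotype and a symbol that is not a predicted, Riken or pseudogene name; and, from each list, the 3 members with the smallest adjusted p and the member with the highest mean CPM. Some genes that the rule takes are not reported here. Genes named outside this rule are said to have been chosen after their values were seen, except antisense partners, which are named for their overlap.

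Gene types, strands, neighbours, GC content and transcript length came from the GENCODE M21 annotation of build GRCm38. This is another build than that of the counts, so no coordinates are given. Of the genes tested, 12844 (98.4%) matched by identifier.

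The procedure was tested on simulated counts with known changes planted among 12709 genes of this comparison. It recovered 40.9% of genes changed 1.5-fold, 63.6% changed 2-fold and 84.6% changed 4-fold, and 8.82% of its 136 calls were unchanged genes, above the nominal 5%. The planted list was called and 0 of 20 null lists were. The simulation drew genes independently and planted all genes of that list upward, so it does not test lists whose genes vary together. It changed 66, 66 and 65 tested genes by these sizes, far fewer than the 2400 genes called in the data. Its rates may therefore not carry over.

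Alternatives planned before the data were examined were DESeq2 size factors, upper-quartile scaling, library size only, removal of globin genes, no filter, a filter of at least 10 CPM in 2 libraries, DESeq2 1.42.0, limma voom, leaving out each library, the replicate number as a block, a GC content offset, both together, glmTreat against a 1.5-fold change, an estimated correlation, fry, which tests each list against no change and not against the other genes, and lists without shared genes. Added after the data were seen were a transcript length offset, the removal of immunoglobulin genes, limma voom with a variance weight per genotype, and an edgeR likelihood ratio test with an assumed biological coefficient of variation of 0.2. Shares of counts were compared by an exact permutation test, which with 2 against 2 libraries cannot go below p = 0.333. Groups of 2 are too small for a test of other splits of the samples.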

Results

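Ter119+ erythroid cells from the bone marrow of mice with floxed Med16 (fl/fl) or with Med16 knocked out (KO) were profiled by poly(A) RNA sequencing, with 2 libraries per genotype. The comparison asks how loss of this Mediator subunit changes the transcriptome of the erythroid fraction. The libraries held between 6749196 and 7216333 counts assigned to genes. At this similar depth, 18947 and 19016 genes had at least 1 count in the fl/fl libraries, against 16892 and 16479 in the KO libraries. The labels do not state that libraries of a genotype came from separate animals, so all p values below measure the spread between these libraries, which may be technical.

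The libraries differed from each other by more than sampling noise. The chi-square statistic per degree of freedom over genes was 2.73 between the fl/fl libraries and 6.63 between the KO libraries, against 18.3 to 20.3 between genotypes. Each library was counted as 1 replicate. The statistic sets differences against counting noise alone, so it cannot show that the libraries came from separate animals. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.983 within fl/fl, 0.956 within KO and 0.942 to 0.947 between genotypes. The first principal component held 57.2% of the variance and separated the genotypes, and the second held 30.9% and separated the KO libraries.

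Med16 itself fell in the KO libraries, from 20.8 ± 3.40 to 3.33 ± 1.53 CPM (mean ± SD, n = 2 per genotype, as in all values below). Its counts were 164 and 127 in the fl/fl libraries and 16 and 30 in the KO libraries, so the gene with the identifier ENSMUSG00000013833 followed the labels in all 4. The log2 fold change was -2.64 (SE 0.34, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.6e-05). Which exons were deleted is not stated in the labels.

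Of 13052 genes tested, 2400 changed, with 1109 higher and 1291 lower in Med16 KO (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). The changes were mostly small: 205 genes rose and 147 fell by a log2 fold change of at least 1, and the median size among called genes was 0.55. With library size as the only scaling, 1365 were higher and 1055 lower, so the share called higher was 56.4% in place of 46.2%. Fits without 1 library take their spread from the 2 libraries of the other genotype alone. Fewer genes were called without either fl/fl library and more without either KO library, and the KO libraries differed more from each other than the fl/fl libraries did. Calls that end or appear in such fits, here and below, therefore do not show that the library left out was unstable. With a biological coefficient of variation of 0.2 assumed in place of the estimate, an alternative chosen after the data were seen, 620 genes were called and 379 of the 2400 were kept.

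**Figure D1:**
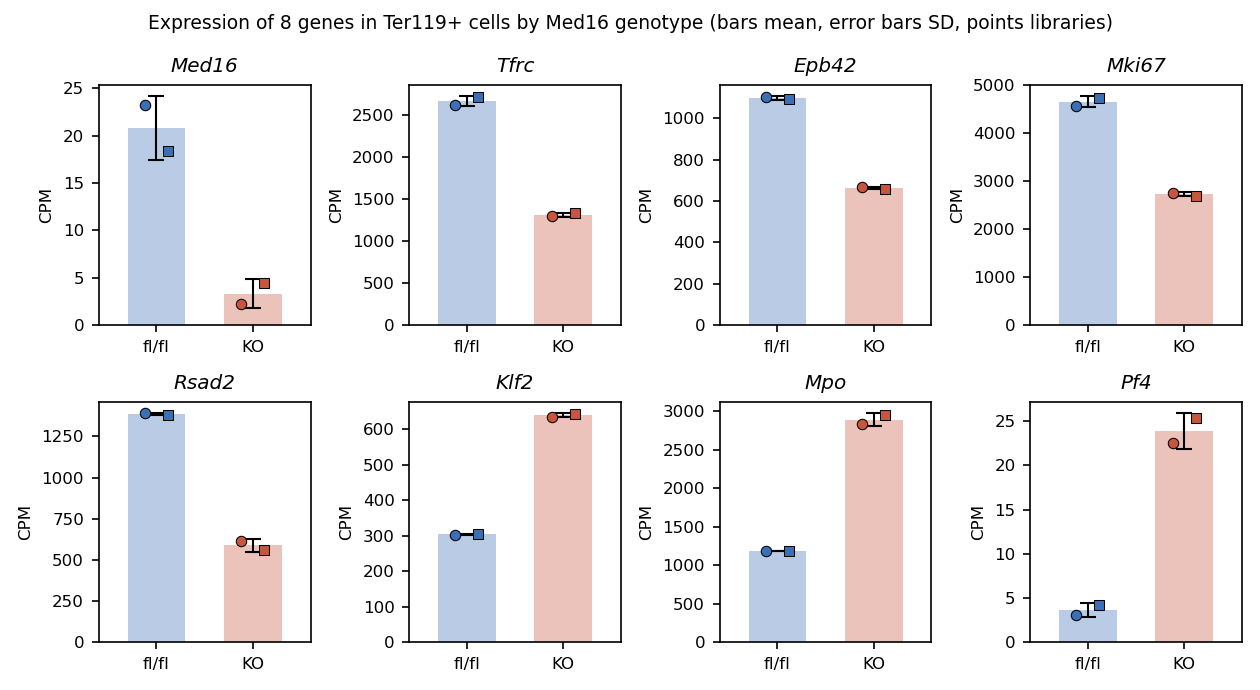
TMM-scaled CPM (vertical axes, each from 0) of 8 genes in the Med16 fl/fl (blue) and Med16 KO (red) libraries; bars are means, error bars SD, circles library 1 and squares library 2. Med16 fell from 20.8 to 3.33 CPM, Tfrc, Epb42, Mki67 and Rsad2 were also lower in both KO libraries, and Klf2, Mpo and Pf4 were higher in both.

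Genes of the red cell membrane and skeleton fell together. Of 27 tested, 25 were lower in Med16 KO and none higher (26 lower when adjusted over the list alone), with a median log2 fold change of -0.41. The protein 4.2 gene Epb42 fell from 1099 ± 9.74 to 662 ± 5.59 CPM (log2 fold change -0.73, SE 0.04), and the band 3 anion exchanger gene Slc4a1 from 13292 ± 60.7 to 10035 ± 84.7 CPM (-0.41, SE 0.02). Camera called this list lower (adjusted p = 4.8e-31), with adjusted p = 0.068 with an estimated correlation.

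Most called genes of haem synthesis and iron handling were lower. Of 31 tested, 15 were lower and 2 higher (16 and 3 when adjusted over the list alone). With a GC content offset or a transcript length offset, 16 were lower and none higher. The transferrin receptor gene Tfrc, through which erythroid cells take up iron, fell from 2670 ± 60.1 to 1314 ± 22.5 CPM (log2 fold change -1.02, SE 0.03). The mitochondrial iron importer gene Slc25a37 fell from 3970 ± 53.7 to 2102 ± 51.6 CPM (-0.92, SE 0.03). Alas2, the erythroid enzyme that starts haem synthesis, rose slightly from 10313 ± 164 to 11252 ± 151 CPM (0.13, SE 0.02), a call that ended with a GC content offset at 0.02 and with a transcript length offset at 0.05. As a whole these genes were called lower (camera adjusted p = 5.8e-10; adjusted p = 0.094 with an estimated correlation).

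Among 22 erythroid transcription regulators, 12 were lower and none higher (12 lower and 1 higher when adjusted over the list alone). Without KO library 1, 2 were higher and 11 lower, and without KO library 2, 1 was higher and 12 lower. Sox6 fell from 438 ± 4.11 to 269 ± 12 CPM (log2 fold change -0.71, SE 0.06), and Klf1, an activator of erythroid genes, from 631 ± 16.2 to 416 ± 4.04 CPM (-0.60, SE 0.05). Foxo3 fell by 0.56 and E2f2, the most abundant member, by 0.22 on the log2 scale. The call of this list had a camera adjusted p = 2.9e-06, and adjusted p = 0.095 with an estimated correlation. Of 29 genes of terminal maturation, enucleation and organelle clearance, 10 were lower and 4 higher (12 and 6 when adjusted over the list alone). Those higher were 2 without fl/fl library 1 or 2 and 7 without KO library 1. Xpo7, a nuclear exporter used during nuclear condensation, fell from 2417 ± 139 to 1267 ± 54.6 CPM (-0.93, SE 0.04), Trim10 fell by 0.62 and Wdr26 by 0.40 on the log2 scale. The most abundant member, Ube2l6, was called higher with a log2 fold change of 0.10 (SE 0.03); that call ended with DESeq2 size factors at 0.097, with a transcript length offset at 0.02, and without fl/fl library 1 at 0.089, fl/fl library 2 at 0.096 or KO library 2 at 0.055. This list had a camera adjusted p = 0.0043 for a lower level, and adjusted p = 0.351 with an estimated correlation.

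Globin transcripts took 16.2 ± 0.00559% of assigned counts in fl/fl and 16.9 ± 0.578% in KO, which the exact permutation test cannot separate (two-sided p = 0.333, the smallest it allows). Among 6 globin genes tested, 2 were higher and 1 lower (2 and 2 when adjusted over the list alone). The lower count was 2 with DESeq2 size factors or without fl/fl library 1 or 2, and 3 without KO library 2. Hba-a2 was higher (log2 fold change 0.44, SE 0.06), as was Hba-a1 (0.21, SE 0.04), and the most abundant globin gene, Hbb-bs, was lower (-0.17, SE 0.03). These genes have near-identical copies and are uncertain, and the call of Hba-a1 ended with a GC content offset at 0.00091. The list was not called (camera adjusted p = 0.884).

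Cell cycle genes were lower in Med16 KO. Of 31 genes of G2 and M phase, 22 were lower and none higher (27 lower when adjusted over the list alone), with a median of -0.37. Top2a, the topoisomerase that resolves chromosomes, fell from 1083 ± 7.02 to 705 ± 29.2 CPM (log2 fold change -0.62, SE 0.04), Cenpf by 0.74 and the spindle motor gene Kif11 by 0.65 on the log2 scale. Of 29 S phase genes, 13 were lower and none higher (14 lower when adjusted over the list alone): Pcna, the sliding clamp of DNA polymerase, fell from 680 ± 8.94 to 510 ± 13.0 CPM (-0.42, SE 0.05), Ccne2 by 0.81 and Rrm2 by 0.36 on the log2 scale. Both lists were called lower, with camera adjusted p = 9.5e-18 for G2 and M phase and 1.8e-06 for S phase, and adjusted p = 0.068 and 0.095 with an estimated correlation. Of 11 CDK inhibitors and genes of cell cycle exit, 6 were also lower and none higher, over all genes and adjusted over the list alone (1 higher with library size as the only scaling). Cdkn1b fell by 0.58, Cdkn2d by 0.52 and Rb1, which restrains entry into S phase, by 0.37 on the log2 scale. Btg2, the most abundant member, was lower at -0.28 and no longer called without fl/fl library 1, at -0.22. This list was called lower (camera adjusted p = 0.011; adjusted p = 0.228 with an estimated correlation).

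The early erythroid progenitor list went both ways, with 6 of 23 genes higher and 6 lower, over all genes and adjusted over the list alone. Those higher were 3 without fl/fl library 1 and 1 without fl/fl library 2. The proliferation marker Mki67 fell from 4655 ± 119 to 2728 ± 38.5 CPM (log2 fold change -0.77, SE 0.03), the carbonic anhydrase gene Car2 from 5984 ± 115 to 4194 ± 34.2 CPM (-0.51, SE 0.03) and Cd24a from 4901 ± 37.8 to 3471 ± 43.3 CPM (-0.50, SE 0.03). The list's median was 0.26 and its mean 0.03, while the test pointed lower without a call (camera adjusted p = 0.144; fry, which tests against no change and not against the other genes, called it lower at 0.022).

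Interferon response genes were lower. Of 34 tested, 16 were lower and none higher (21 lower when adjusted over the list alone), with a median log2 fold change of -0.94. Rsad2, which encodes the antiviral protein viperin, fell from 1385 ± 5.79 to 590 ± 40.5 CPM (-1.23, SE 0.05), the ubiquitin-like modifier gene Isg15 from 201 ± 9.45 to 73.4 ± 6.07 CPM (-1.46, SE 0.09), and Oas3 from 174 ± 1.13 to 75.5 ± 11.8 CPM (-1.21, SE 0.10). Chosen after their values were seen, the transcription factor genes Irf7 and Irf9 fell by 1.04 and 1.22, and Stat2 by 0.99 on the log2 scale. Mx1, Zbp1 and Ifit2, chosen in the same way, had log2 fold changes of -0.02, 0.09 and -0.13 that were not past the threshold. Interferon genes as a list were called lower (camera adjusted p = 2.3e-17; adjusted p = 0.095 with an estimated correlation).

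Immediate early genes, which handling can raise and which were fixed as a quality list, were higher, 13 of 19 with none lower (15 higher when adjusted over the list alone). The transcription factor gene Klf2 rose from 304 ± 0.598 to 640 ± 5.76 CPM (log2 fold change 1.07, SE 0.05), the AP-1 gene Fosb from 344 ± 13.3 to 586 ± 10.6 CPM (0.77, SE 0.05), and Zfp36, which encodes an mRNA decay factor, from 619 ± 31.3 to 890 ± 7.68 CPM (0.52, SE 0.05). Jund, the most abundant member, rose by 0.36, but with the strand setting unknown its reads cannot be told from those of the antisense gene Gm11175. Immediate early genes as a list were called higher (camera adjusted p = 1.4e-17; adjusted p = 0.068 with an estimated correlation), and its median of 0.44 was 0.24 with a GC content offset.

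Glycolysis genes were higher for 10 of 23 entries and lower for none (11 higher and 2 lower when adjusted over the list alone), counting 2 identifiers of Aldoa. Lower were 1 without fl/fl library 2, 2 without KO library 1 and 3 without KO library 2. Gpi1 rose by 0.73, Pkm by 0.65 and the main Aldoa entry by 0.64 on the log2 scale, while Bpgm, which makes the 2,3-bisphosphoglycerate of red cells, had a log2 fold change of -0.08 (SE 0.03) that was not past the threshold. The list was called higher (camera adjusted p = 1.2e-06; adjusted p = 0.162 with an estimated correlation), and its median of 0.48 was 0.26 with a GC content offset. Of 62 ribosomal protein genes, 27 were higher and 1 lower (33 and 1 when adjusted over the list alone), with a median of 0.17. Those higher were 16 without fl/fl library 1, 9 without fl/fl library 2 and 11 with a transcript length offset. None were lower without fl/fl library 1 or 2 or KO library 1, and 2 were without KO library 2. Rps9 rose by 0.34, Rps15 by 0.38, Rpl41 by 0.29 and Rplp0 by 0.19 on the log2 scale. The calls of Rps15 and Rplp0 ended with a GC content offset at 0.12 and 0.10, and that of Rplp0 also with a transcript length offset at 0.10. This list was called higher (camera adjusted p = 4.1e-07; adjusted p = 0.312 with an estimated correlation), and its median was 0.10 with a GC content offset and 0.06 with a transcript length offset. Of 10 mitochondrially encoded genes, also fixed as a quality list, 5 were higher and none lower, over all genes and adjusted over the list alone (2 higher and 1 lower without fl/fl library 1, 4 and 1 without KO library 2): mt-Nd1 rose by 0.46 and mt-Nd2 by 0.33 on the log2 scale, and mt-Nd4 was at 0.26, no longer called without fl/fl library 1 at 0.18. The most abundant, mt-Co1, had a log2 fold change of -0.07 that was not past the threshold, and 0.12 past it with a GC content offset. The list was called higher (camera adjusted p = 0.0084; adjusted p = 0.445 with an estimated correlation), except without fl/fl library 1 (adjusted p = 0.087), with a transcript length offset (0.146) and by fry (0.122). Mitochondrially encoded genes took 0.794 ± 0.0393% of counts in fl/fl and 0.870 ± 0.0198% in KO (exact permutation test, two-sided p = 0.333, the smallest it allows).

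**Figure D2:**
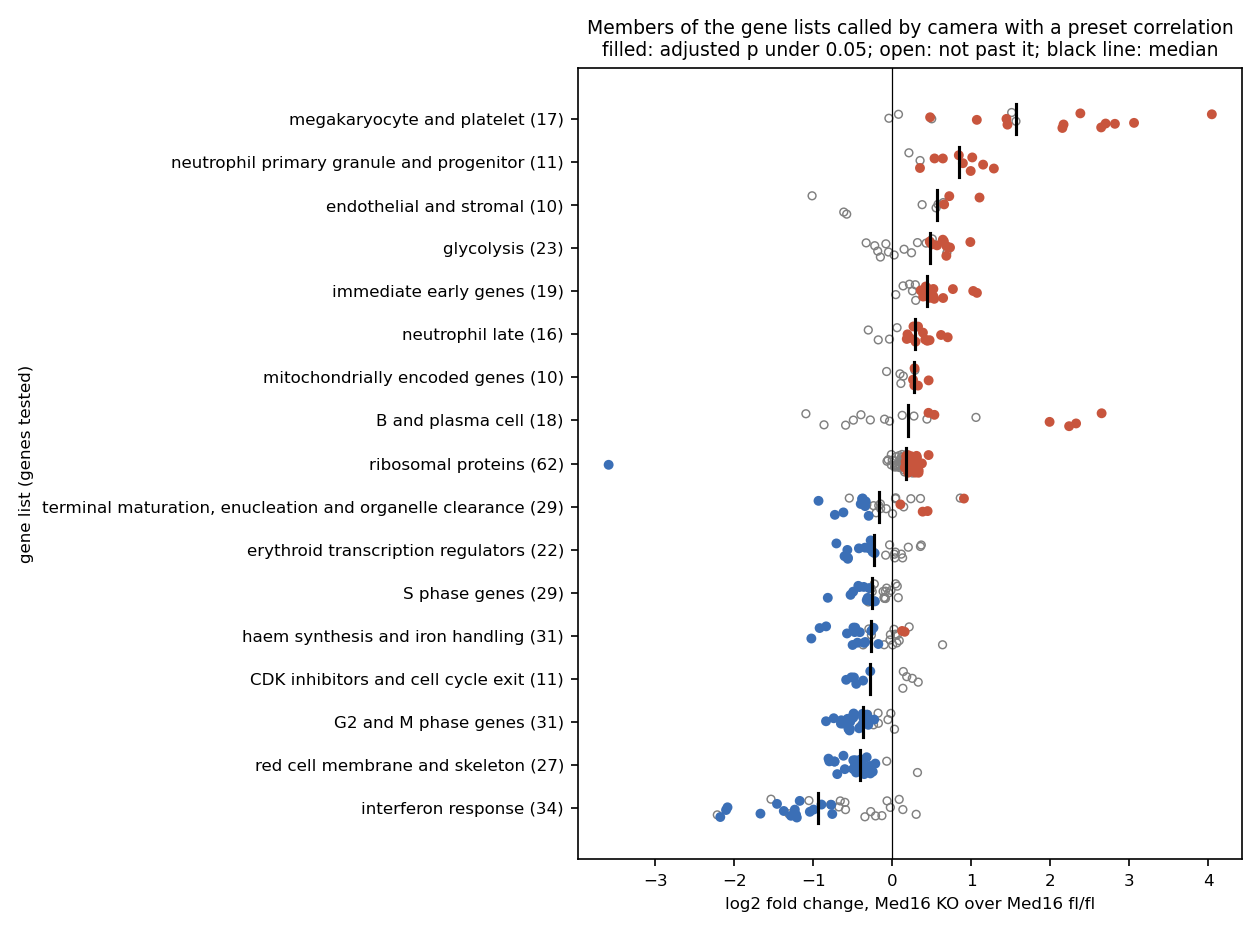
Log2 fold change of Med16 KO over Med16 fl/fl (horizontal axis) for each gene tested of the 17 lists called by camera with a preset correlation (vertical axis); filled points passed the edgeR test, open points did not, and black lines are medians. Medians run from -0.94 for interferon response genes to 1.57 for megakaryocyte and platelet genes, and the ribosomal protein point farthest to the left is Rps10, chosen after its values were seen, at 1.93 against 0.147 CPM.

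Markers of other marrow cells moved with genotype as well. Of 17 megakaryocyte and platelet genes, 12 were higher and none lower (14 higher when adjusted over the list alone), with a median of 1.57. The higher count was 7 of 17 without fl/fl library 1 and 5 of 18 without fl/fl library 2, with medians of 1.99 and 1.49. Itga2b, the platelet integrin gene, rose from 26.1 ± 2.29 to 71.9 ± 0.993 CPM (log2 fold change 1.46, SE 0.14), and the platelet chemokine genes Ppbp from 3.43 ± 0.955 to 24.4 ± 0.115 CPM (2.82, SE 0.29) and Pf4 from 3.66 ± 0.771 to 23.9 ± 2.0 CPM (2.70, SE 0.29). The most abundant member, Thbs1, had a log2 fold change of 0.08 that was not past the threshold. The list was called higher (camera adjusted p = 2.2e-09; adjusted p = 0.095 with an estimated correlation).

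Neutrophil genes rose too. Of 11 genes of the primary granule and of neutrophil progenitors, 9 were higher and none lower (10 higher when adjusted over the list alone), with a median of 0.84. The myeloperoxidase gene Mpo rose from 1185 ± 2.60 to 2893 ± 83.4 CPM (log2 fold change 1.29, SE 0.03), the elastase gene Elane from 387 ± 1.90 to 781 ± 5.85 CPM (1.01, SE 0.05) and the proteinase 3 gene Prtn3 from 284 ± 7.34 to 566 ± 14.3 CPM (0.99, SE 0.05). Elane and Prtn3 lie within 3 tested genes of Med16. Gm11505, an antisense partner that overlaps Mpo over 69.5% of its exon length, was at 1.30 on the log2 scale. With the strand setting unknown, reads of Mpo in the overlap cannot be told from those of Gm11505. Of 16 late neutrophil genes, 12 were higher and none lower, over all genes and adjusted over the list alone, with a median of 0.28: Cd177 rose by 0.70, Mmp9 by 0.62, S100a8 by 0.45 and S100a9, the most abundant, by 0.42 on the log2 scale. Without KO library 1, 1 late neutrophil gene was lower. Both lists were called higher, with camera adjusted p = 3.2e-26 for the primary granule and 2.2e-08 for late neutrophils, and adjusted p = 0.068 and 0.095 with an estimated correlation.

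Monocyte and macrophage genes went both ways, with 5 of 22 higher and 3 lower, over all genes and adjusted over the list alone (none lower without fl/fl library 1 or 2, and 1 with library size as the only scaling), and the list was not called (camera adjusted p = 0.20). Lyz2 rose by 0.53, Ly6c2 by 0.54 and Cd14 by 0.96 on the log2 scale. Of 10 endothelial and stromal genes, 3 were higher and none lower (4 higher when adjusted over the list alone, and 5 of 13 without KO library 2): Col1a1 rose by 1.11, Apoe by 0.66 and Col1a2 by 0.72 on the log2 scale. That list was called higher (camera adjusted p = 0.0084; adjusted p = 0.228 with an estimated correlation). No call was made for mast cell, basophil and eosinophil genes (2 of 15 lower, 1 when adjusted over the list alone or with library size as the only scaling, and 1 higher without KO library 1; camera adjusted p = 0.408), T and NK cell genes (2 of 12 higher, 0 when adjusted over the list alone, and 1 lower without KO library 2; 0.415) or stem and progenitor genes (2 of 12 higher, also adjusted over the list alone, and 1 lower without KO library 1; 0.176, and 0.012 by fry). Ear1 was lower at -0.66, not called without fl/fl library 2 at -0.64, and Mcpt8 was lower at -0.69, not called without fl/fl library 1 at -0.60 or fl/fl library 2 at -0.80. Prg2, an abundant eosinophil gene, had a log2 fold change of 0.04 that was not past the threshold. Ly6a was higher at 1.69, not called without fl/fl library 1 at 1.75 or fl/fl library 2 at 1.6, and Cd34 was higher at 1.08, not called without fl/fl library 2 at 0.72 or KO library 1 at 0.60. Cd28 and Ccl5, at 1.88 and 1.56, were not called without fl/fl library 1 (1.70 and 1.30), fl/fl library 2 (2.05 and 1.84) or KO library 1 (1.37 and 1.20).

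The B and plasma cell list was called higher (camera adjusted p = 1.7e-17; adjusted p = 0.068 with an estimated correlation), with 6 of 18 genes higher and none lower (7 higher and 1 lower when adjusted over the list alone). Without KO library 1, 2 were lower, and without KO library 2, 1 was. Ighm, the constant gene of IgM, rose from 668 ± 17.6 to 3157 ± 3.44 CPM (log2 fold change 2.24, SE 0.04), the kappa constant gene Igkc from 217 ± 1.17 to 866 ± 32.1 CPM (1.99, SE 0.05) and the joining chain gene Jchain from 60.1 ± 3.13 to 302 ± 0.865 CPM (2.33, SE 0.08).

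Immunoglobulin genes made up the 10 largest rises of all genes under the naming rule. Of 91 V segments tested, 50 were higher and 9 lower, and each of these differed by a log2 fold change of at least 1 in size. Ighg3, the constant gene of IgG3, had no count in either fl/fl library and 27.5 ± 6.39 CPM in KO, at least 63.3-fold higher against a floor of 3 counts per library. The others were Ighv1-4 (0.143 against 33.7 CPM), Ighv1-9 (0.0725 against 17.6 CPM), Igkv4-50 (0.142 against 31.3 CPM), Ighv1-75 (0.430 against 54.1 CPM), Ighv1-12 (0.0708 against 10.4 CPM), Igkv3-4 (0.287 against 33.8 CPM), Igkv6-20 (0.0725 against 9.67 CPM), Igkv5-48 (0.142 against 14.9 CPM) and Ighv1-58 (0.0725 against 6.02 CPM), means of fl/fl against KO. Other immunoglobulin genes fell: Igkv14-100 went from 24.3 ± 1.41 CPM to no count in either KO library, at least 55.2-fold lower, and Igkv3-2 from 5.51 ± 0.413 CPM to no count, at least 12.5-fold lower. Ighv5-2 fell from 13.6 ± 2.61 to 0.288 ± 0.00944 CPM, Ighg2b from 21.6 ± 0.444 to 1.29 ± 0.161 CPM, and Igkv4-74 from 5.51 ± 1.22 to 0.140 ± 0.199 CPM, which was not called without fl/fl library 1. V segments share sequence, so single segments are uncertain. Across the 91 segments, which are not independent, Pearson's r of log2 CPM was 0.910 between the fl/fl libraries, 0.926 between the KO libraries and -0.172 to -0.138 between genotypes. A segment could pass the expression filter through 1 genotype alone, and segments low in both were left out. This choice lowers r between genotypes and can raise it within a genotype, so the sizes of r depend on it.

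**Figure D3:**
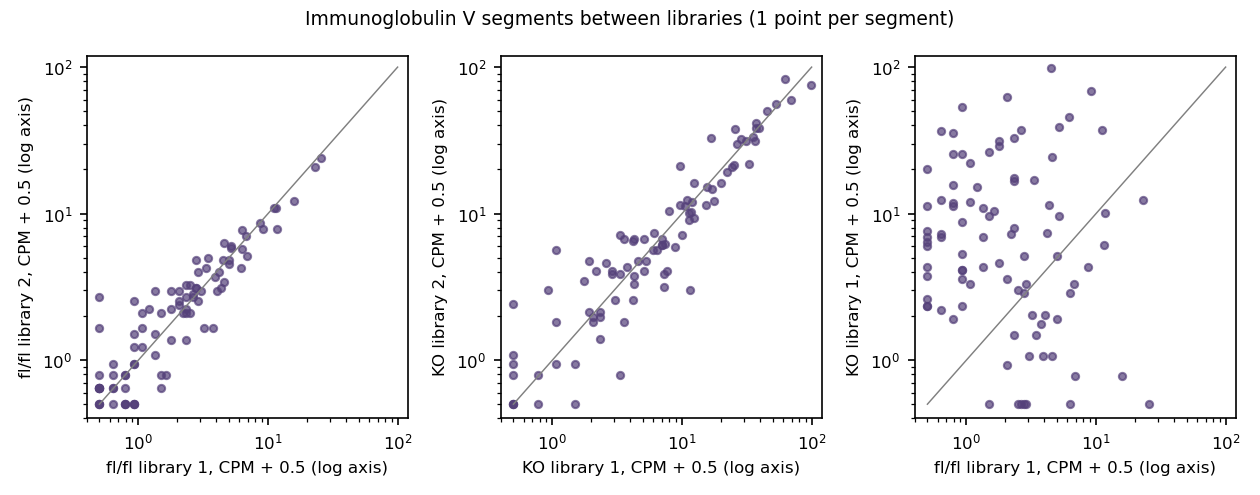
CPM plus 0.5 of 91 immunoglobulin V segments (1 point each, log axes) in fl/fl library 2 against fl/fl library 1, KO library 2 against KO library 1, and KO library 1 against fl/fl library 1; the line marks equal values. Points follow the line within a genotype (r of 0.910 and 0.926) and not between genotypes (r of -0.145). Segments low in both genotypes were left out by the expression filter, which lowers r between genotypes.

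Outside the immunoglobulin genes, the largest falls under the naming rule were Hspa1b (49.5 ± 2.91 to 1.59 ± 0.865 CPM, log2 fold change -4.95, SE 0.29), Aknad1 (5.59 ± 0.703 to 0.715 ± 0.180 CPM), Denn2b (88.0 ± 13.3 to 13.0 ± 2.01 CPM, -2.75, SE 0.17), Ace (7.46 ± 1.14 to 1.15 ± 0.241 CPM) and Med16. Aknad1, at -2.93, was not called without fl/fl library 1 at -3.07 or fl/fl library 2 at -2.81, and Ace, at -2.68, was not called without fl/fl library 2 at -2.52. With immunoglobulin genes set aside, a choice made after the data were seen, the largest rises outside the fixed lists were Fscn1 (0.287 ± 0.00486 to 5.63 ± 2.76 CPM, 4.22, SE 0.78) and Derl3 (0.716 ± 0.0121 to 6.71 ± 1.95 CPM, 3.20, SE 0.60). Fscn1 was at 7.58 CPM in KO library 1 and 3.68 CPM in KO library 2. The largest further falls included the peptide transporter gene Slc15a2 (-2.27, SE 0.25) and the chemokine receptor gene Ccr3 (-2.14, SE 0.35).

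The remaining lists were not called by camera. Of 33 Mediator subunits, 7 were lower and none higher, over all genes and adjusted over the list alone (camera adjusted p = 0.20, and 0.045 by fry). The lower count was 3 without fl/fl library 1 and 2 without fl/fl library 2, and 1 was higher without KO library 1 or with library size as the only scaling and 2 without KO library 2. Besides Med16, the kinase module gene Med13 fell by 0.48 on the log2 scale. Med19 was lower at -0.73, not called without fl/fl library 2 at -0.66, and Med13l was lower at -0.32, not called without fl/fl library 1 at -0.34, fl/fl library 2 at -0.33 or with a transcript length offset at -0.21. The unfolded protein and heat shock list had 5 of 22 genes higher and 7 lower (6 and 7 when adjusted over the list alone; camera adjusted p = 0.20, and 0.016 by fry), a median of 0.14 and a mean of -0.20. Its counts were 2 and 6 without fl/fl library 1, and 1 and 5 without fl/fl library 2. Besides Hspa1b, its paralog Hspa1a fell from 31.7 ± 4.63 to 8.63 ± 0.486 CPM (-1.88, SE 0.23) and the constitutive chaperone gene Hspa8 by 0.46 on the log2 scale; the Hspa1 paralogs are uncertain. The ATF4 and integrated stress response list had 2 of 22 genes higher and 7 lower (4 and 9 when adjusted over the list alone; camera adjusted p = 0.205, and 0.0072 with a GC content offset). These counts were 1 and 3 without fl/fl library 1, 1 and 4 without fl/fl library 2, 4 and 9 without KO library 1, and 3 and 4 with library size as the only scaling. Its asparagine synthetase gene Asns fell by 1.12 and Atf4 by 0.28, while Cebpb rose by 0.52 on the log2 scale.

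Of 23 antioxidant genes, 5 were higher and 8 lower (6 and 8 when adjusted over the list alone; 2 higher without fl/fl library 1 or 2; camera adjusted p = 0.408): Gclc, of glutathione synthesis, fell by 0.63, Prdx3 by 0.55, Gclm by 0.36 and Gpx1 by 0.17 on the log2 scale. Of 44 genes of chromatin remodelling and histone modification, 4 were higher and 14 lower (4 and 16 when adjusted over the list alone; camera adjusted p = 0.085, 0.017 with a GC content offset, and 0.023 by fry): Kmt2a fell by 0.88, Kdm6a by 0.58 and Rbbp4 by 0.37 on the log2 scale. The chromatin counts were 1 and 6 without fl/fl library 1, 1 and 3 without fl/fl library 2, 7 and 16 without KO library 1, and 4 and 7 with library size as the only scaling. Of 20 genes of the erythropoietin and STAT5 response, 4 were higher and 2 lower (8 and 3 when adjusted over the list alone; camera adjusted p = 0.085, and 0.039 without fl/fl library 1). The erythropoietin counts were 1 and 2 without fl/fl library 1, 0 and 2 without fl/fl library 2, 8 and 3 without KO library 1, and 8 and 2 with library size as the only scaling. Bcl2l1, which protects erythroid cells from apoptosis, fell by 0.26 and the erythropoietin receptor gene Epor by 0.34 on the log2 scale. Mcl1 was at 0.21, not called without fl/fl library 1 at 0.21 or fl/fl library 2 at 0.19. Of 20 p53 targets, 2 were lower and none higher, also when adjusted over the list alone (1 higher without KO library 1 and 3 without KO library 2; camera adjusted p = 0.913): Sesn1 was at -0.46, not called without fl/fl library 2 at -0.37, and Apaf1 was at -0.43, not called without fl/fl library 1 at -0.44 or fl/fl library 2 at -0.45. Of 45 oxidative phosphorylation genes, 5 were higher and none lower over all genes, and 0 when adjusted over the list alone (none higher without fl/fl library 1 or 2, 3 with upper-quartile scaling, and 9 without KO library 2, with 1 lower without KO library 1 or 2; camera adjusted p = 0.190). Atp5a1, Atp5c1 and Ndufb7, at 0.17, 0.32 and 0.40, were not called without fl/fl library 1 (0.14, 0.34 and 0.43) or fl/fl library 2 (0.17, 0.27 and 0.34), and Atp5b, at 0.03, was not past the threshold. Of the 4 sex-linked genes tested, Ddx3y and Uty were lower at -0.38 and -0.84, calls that ended without fl/fl library 1 (-0.39 and -0.66) or fl/fl library 2 (-0.38 and -1.02) and with library size as the only scaling, and Eif2s3y, at -0.15, was not past the threshold.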

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

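Reads outside the gene counts differed between genotypes. Reads that were not aligned made up 2.98 ± 0.41% of all reads in the KO libraries, above 0.936 ± 0.155% in the fl/fl libraries, and stood out because both KO libraries lay above both fl/fl libraries. Reads that fell on more than 1 gene did the same, at 2.94 ± 0.0246% in KO and 2.56 ± 0.0273% in fl/fl. With 2 against 2 libraries the exact permutation test gave p = 0.333 for each (two-sided, the smallest it allows), while the gaps of 2.05 and 0.387 percentage points were wider than the SD of either genotype. Other classes were lower in both KO libraries than in both fl/fl libraries: reads without a unique alignment (24.0 ± 0.479% against 25.8 ± 0.787%), reads assigned to no feature (35.8 ± 0.000707% against 36.3 ± 0.496%) and reads with low alignment quality (1.69% and 1.70% against 1.79% and 1.96%). These reads enter no comparison of genes.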

How the results depend on the processing

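The transcript length offset, the removal of immunoglobulin genes, the voom variance weight per genotype and the assumed biological coefficient of variation were chosen after the data were seen. The count of 2400 changed genes stayed between 1932 and 2767 under the scaling, filter, tool, block, GC, length and immunoglobulin alternatives. Leaving out 1 library gave 1158 to 3998 (454 to 1839 higher, 704 to 2172 lower; 113 to 448 higher and 72 to 529 lower by a log2 fold change of at least 1); fewer libraries enter these fits and the lone library is assumed to vary like the others. glmTreat against a 1.5-fold change gave 149 (84 higher, 65 lower; 73 and 48 by at least 1), by its construction. The assumed coefficient of 0.2 gave 620 (331 and 289; 311 and 270 by at least 1). With at least 10 CPM in 2 libraries, 105 rose and 79 fell by at least 1, with fewer genes tested. With the GC content offset, 1643 of the 2400 calls kept their sign and threshold and 15 changed sign. With an estimated correlation 0 of the 17 lists were called, and the lowest adjusted p was 0.0683. On 2 residual degrees of freedom this setting had little power. It cannot decide whether correlation between genes accounts for the calls. The 17 list calls kept their direction in every list alternative that called them. For the 500 most variable genes, the mean correlation within minus between genotypes was 0.592 in place of 0.0249. These genes were selected by their variance over the same 4 libraries, which favours genes that differ between genotypes, so no conclusion is drawn from this rise. The cause of the differences between settings was not tested otherwise.

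The replicate number did not pair the libraries (correlation of same-numbered deviations -0.0102 over 13052 genes); as a block it gave 2767 calls, and 1973 together with the GC content offset. Values that changed sign were small. With the GC content offset, log2 fold changes were -0.0282 for Atp5b, 0.118 for mt-Co1, 0.0363 for Eif2s3y and -0.0516 for Prg2; with block and offset together they were -0.00111 for Hba-a1, -0.0281 for Atp5b, 0.118 for mt-Co1, 0.0368 for Eif2s3y and -0.0499 for Prg2; with the length offset they were -0.0402 for Atp5b and -0.083 for Prg2. Leaving out 1 library, Prg2 ranged from -0.044 (without fl/fl library 2) to 0.113. Uncalled lists whose direction turned had these adjusted p values: globins 0.404 to 0.715 leaving out 1 library (turned without fl/fl library 1 or KO library 2), 0.322 with the GC content offset, 0.153 with block and offset, and 0.281 with the length offset; p53 targets 0.845 without a filter, 0.613 to 0.936 leaving out 1 library (turned without KO library 2), and 0.925 with the GC content offset, with or without the block; early erythroid genes 0.671 and unfolded protein genes 0.791 without a filter. Lists called only under other settings were, by adjusted p, erythropoietin and STAT5 response (0.0057 without a filter, 0.036 by voom, 0.039 without fl/fl library 1), oxidative phosphorylation (0.043 without a filter), stem and progenitor genes (0.031 without a filter, 0.012 by fry), chromatin (0.018 without a filter, 0.017 with the GC content offset, 0.018 with block and offset, 0.045 by voom, 0.023 by fry), ATF4 (0.0072 with the GC content offset, 0.0063 with block and offset), and, by fry, which asks whether a list changed at all, Mediator subunits (0.045), early erythroid progenitor genes (0.022) and unfolded protein genes (0.016); fry called 21 lists, 16 of them among the 17. Calls of named genes ended for 20 genes without fl/fl library 1, 22 without fl/fl library 2, 3 without KO library 1, 2 without KO library 2, 11 with the GC content offset, 11 with block and offset, 10 with the length offset, 3 each by DESeq2, voom and library size only, 2 each without a filter and by voom with the weight per genotype, 1 each with DESeq2 size factors and upper-quartile scaling, and 75 with the assumed coefficient. Of 2695 values of named genes under alternatives, 2480 kept direction and side of the threshold. Depth limits genes near 0.4 CPM.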

Other observations

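The tests of explanations in this part were chosen after the results they bear on were seen, and the genes named here outside the naming rule were chosen after their values were seen.

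Immunoglobulin constant genes differed by class between the genotypes. Igha, of IgA, fell from 61.1 ± 3.32 to 31.7 ± 6.32 CPM (log2 fold change -0.95, SE 0.16), and Ighg2c had a log2 fold change of -0.34 that was not past the threshold. Ighd, of IgD, rose from 15.5 ± 1.18 to 25.4 ± 1.34 CPM (0.71), not called without fl/fl library 1 at 0.62 or fl/fl library 2 at 0.78, with glmTreat or with the assumed coefficient of variation, and the lambda genes Iglc1 and Iglc2 rose from 7.89 ± 1.76 to 54.8 ± 4.85 and from 4.53 ± 2.20 to 28.5 ± 7.60 CPM. Plasma cell genes outside these loci were higher for 5 of 10 tested and lower for none, against 3 of 12 higher without fl/fl library 1 or 2, 6 of 11 without KO library 1, and 7 of 11 higher and 1 lower without KO library 2. Of the 10, 2 are also in the B and plasma cell list and 2 in other fixed lists. A sort for Ter119 aims to remove plasma cells, but Ighm was at 668 CPM and Jchain at 60.1 CPM in the fl/fl libraries. Txndc5 rose from 34.8 to 92.5 CPM and Edem2 from 19.6 to 32.0 CPM; Edem2, at 0.71 on the log2 scale, was not called without fl/fl library 1 at 0.88, fl/fl library 2 at 0.53 or with a GC content offset at 0.60, with or without the block, and Prdm1, at 1.62, was not called without fl/fl library 1 at 1.96 or fl/fl library 2 at 1.33, by limma voom at 1.62 or with block and GC content offset at 1.69. The calls among 14 B cell genes outside these loci depended on the libraries: 1 was higher and none lower with all 4, none was called without fl/fl library 1 or 2, 2 were higher and 3 lower without KO library 1, 1 was higher and 1 lower without KO library 2, and 1 was higher and 2 lower with the replicate block. Of the other alternatives, 1 was lower without a filter, with at least 10 CPM in 2 libraries, by limma voom with or without the weight per genotype, and with block and GC content offset. Cd79a rose by 0.46 (SE 0.13) on the log2 scale, a call that ended without fl/fl library 1 at 0.39, fl/fl library 2 at 0.51, with a GC content offset at 0.30, with block and GC content offset at 0.31 and with a transcript length offset at 0.37. The calls of Edem2, Prdm1 and Cd79a also ended with glmTreat, and those of Edem2 and Cd79a with the assumed coefficient of variation.

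The first pattern weighed was that V segments matched within a genotype and not between genotypes. V segments at 3 CPM or more differed between the libraries of a genotype by at most 0.702 times the median absolute log2 difference of other genes of like CPM, against about 7 times between genotypes (6.82 to 7.27). The differences were not centred, so a rise common to all segments, such as the 2.24 of Ighm or 1.99 of Igkc, adds to those between genotypes. The sets also differ, with 29 segments within fl/fl, 68 within KO and 71 to 73 between genotypes. A common rise alone would lower no segment, but 9 of the 91 tested were lower, against 50 higher. The match within a genotype goes with a shared animal or cell pool behind its libraries. In that case the p values above would not measure differences between animals. The labels do not settle it. A rise of B lineage cells of all stages is excluded as the whole cause, since 14 B cell genes outside the loci had a median log2 fold change of -0.19 (bootstrap SE 0.21) against 2.24 for Ighm. More plasma cells in the KO fraction stay open as an explanation of the rise of Ighm and Jchain. Without Jchain, Derl3 and Sdc1, whose values had prompted the list, the other 7 plasma cell genes tested had a median of 0.46 (bootstrap SE 0.36). Of 10000 random sets matched on expression, 1.25% reached this median, but the sets draw genes independently. The median also lay below the 2.24 of Ighm, and of the 7 genes 3 were called higher and none lower. This median cannot measure the size of a rise of plasma cells, since genes that other cells also express would rise less. Trp53inp1, also on the p53 list, was at 104 CPM in fl/fl and 88.2 CPM in KO.

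The second pattern was lower erythroid and cell cycle genes with higher myeloid and platelet genes. A lower share of erythroid cells alone would raise all other types alike. The medians of the megakaryocyte and the mast cell, basophil and eosinophil lists lay 1.74 apart (permutation p = 6.5e-04). These were the highest and the lowest median of the cell type lists, and the permutation treats genes of a list as independent. Its p is not corrected for that choice and cannot exclude this cause, although the 2 lists did not move alike. Log2 fold changes rose with GC content over genes (Spearman's rho 0.303 across 12844 genes, which are not independent), but the red cell membrane list kept a median of -0.46 after the GC content offset and -0.41 after the transcript length offset, against -0.41 before, and the megakaryocyte and primary granule lists had medians of 1.67 and 0.68 after the GC content offset, so neither trend is the whole cause. More platelets or neutrophil precursors in the sorted cells, a change of erythroid stage, or a direct effect of Med16 loss on these genes stay open as untested explanations. A difference between animals or pools other than genotype cannot be told apart from an effect of genotype here either. The labels do not show the libraries of a genotype to be separate animals. A sort for Ter119 aims to remove platelets and neutrophil precursors, but their markers were counted in the fl/fl libraries too, with Mpo at 1185 CPM and Pf4 at 3.66 CPM.

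The third pattern was the fall of interferon response genes. The monocyte and macrophage list had a median of 0.03, which lay 0.97 above that of the interferon list (permutation p = 1.1e-04). These genes as a set therefore did not fall with the interferon genes. The permutation treats genes of a list as independent, and 5 of the 22 genes were higher and 3 lower. A fall confined to some of these cells is thus not excluded. GC content bias is excluded as the whole cause, with an interferon median of -0.99 after the offset against -0.94 before. A difference between animals other than genotype, such as an infection, cannot be told apart from an effect of Med16: the genes differed by a median of at most 0.30 on the log2 scale between libraries of a genotype, but the labels do not show these to be separate animals. The effect of genotype thus remains untested against it.

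Gene neighbours and antisense partners gave further values. R3hdm4, next to Med16 among the genes tested, rose from 104 to 179 CPM. This is uncertain, since its antisense partner Gm26602 was at 0.59 on the log2 scale, and 0.49 without fl/fl library 1. The call of Gm26602 ended with a GC content offset at 0.38, with or without the block, and with a transcript length offset at 0.35. Both calls ended with glmTreat and with the assumed coefficient of variation. On the other side of Med16, Gm19810 was at 2.97 (0.287 to 2.37 CPM). The nearby genes Plppr3, Gm17134, Kiss1r, Arid3a and Wdr18 were not past the threshold. Across 121 pairs of a gene and a partner lying at least 90% within its opposite strand exons, the log2 fold changes had a Pearson r of 0.634, and 0.687 across the 24 pairs whose longer gene had a mean of at least 100 CPM; pairs are not independent. The 18S ribosomal RNA gene Rn18s-rs5 took 0.239 ± 0.0582% of counts in KO and 0.127 ± 0.013% in fl/fl (exact permutation test, p = 0.333, two-sided, the smallest it allows). This share, the reads not aligned (2.98% against 0.936%) and the 2 lists fixed as quality signs, immediate early and mitochondrially encoded genes, were all higher in KO. Within the mitochondrially encoded list only 5 of 10 genes were called higher and none lower, and mt-Co1, the most abundant, was at -0.07. Fewer genes had at least 1 count in the KO libraries, 16892 and 16479 against 18947 and 19016 in fl/fl. The labels do not describe the handling of single samples, so a difference in handling between the genotypes was not excluded.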
